A study of Homo sapiens with 12 samples.

How the data were processed

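RNA was sequenced from C4-2 cells, a castration-resistant prostate cancer line derived from LNCaP. Per the labels' protocols, cells received nonspecific or paxillin-directed small interfering RNA (siRNA) for 48 h, were kept without serum for 12 h, and were then given ethanol vehicle or 2.5 nM dihydrotestosterone (DHT) for 24 h. The 4 groups hold 3 libraries each, 12 in all, made with a stranded TruSeq mRNA kit per the labels' protocols. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these samples, which can be technical.

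The authors deposited counts of 56269 gene symbols by 12 libraries, under a name that mentions DESeq2. The values are whole numbers with unequal library totals, so they were taken to be raw counts with no scaling. Per the submitters' processing notes, the tools named were Trimmomatic 0.36, STAR 2.5.2b and featureCounts from Subread 1.5.0p3, with the genome build GRCh38. The annotation release, the strand setting of the counting and the siRNA sequences are not given in the sources used here. Antisense and overlapping genes, paralogs and pseudogenes are therefore reported as uncertain. Library totals ran from 11944906 to 32040465 counts, so that 1 count equals 0.0312 to 0.0837 CPM, the unit of counts scaled to the library total. Levels of genes are given in CPM of the TMM-scaled totals and averaged over the libraries of a group. Floors were set at 3 counts over a group, and 95% intervals of count ratios are exact conditional binomial intervals. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

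Counts were analysed in R 4.3.3 with edgeR 4.0.16. The filter of filterByExpr (minimum count 10, minimum total 15) kept 16115 genes, and libraries were scaled by TMM. A quasi-likelihood model of the 4 group means was fitted to all 12 libraries. DHT was compared with vehicle under each siRNA, paxillin with nonspecific siRNA under each treatment, and the interaction compared the DHT responses. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes carry a standard error (SE) derived from the F statistic. The response ratio is the orthogonal slope through the origin of the DHT log2 fold changes under paxillin siRNA on those under nonspecific siRNA, over genes called for the average DHT effect, with a jackknife spread.

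The groups, tests, 29 gene lists, rule for named genes and most alternatives were chosen before the data were examined. The rule named, per comparison, the 6 largest rises and 6 largest falls among called genes with a group mean of at least 5 CPM and non-overlapping groups. It left out clone, LINC, microRNA and antisense names, and did not require separated groups for the interaction. Chance separates 3 against 3 values in 10% of genes. It also named up to 3 rising and 3 falling called members of each list, and a panel of PXN, TGFB1I1, LPXN, KLK3, TMPRSS2, FKBP5, CCND1, FOS, EGR1 and MYC. Results of some further genes under this rule are not reported here. Of the lists, 28 had at least 5 tested members and were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with Benjamini-Hochberg adjustment over lists within a comparison. Calls were repeated with an estimated correlation and with fry, both without the replicate block described below. Genes were matched by symbol to GENCODE 29 on GRCh38 for coordinates, types, GC content and length, which gave 13977 of the 16115 tested genes a match.

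Replicate numbers in the labels are shared by the 4 groups. Deviations from the group means over 9721 genes correlated at 0.17 to 0.50 in all 18 pairs with the same number, with a median of 0.29. In the 36 pairs with different numbers they ran from -0.44 to 0.22, with a median of -0.13. The numbers were therefore taken to pair the samples, and a fit with the replicate number as a block was run as an alternative. Within groups, replicates differed beyond sampling noise, with chi-square per degree of freedom of 6.16 to 18.6, so all 12 libraries were counted.

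The pipeline was tested on simulated counts for 16115 genes with known changes. For DHT under nonspecific siRNA it called 86% of genes changed 2-fold, and 76% for DHT under paxillin siRNA. It called 86% for paxillin siRNA in vehicle, 82% for paxillin siRNA in DHT and 62% for the interaction. At 1.25-fold the interaction recovered 2%. False calls among the unchanged genes numbered 9, 4, 11, 14 and 7, in the same order of comparisons. The simulation changed 50 genes at each fold and drew replicates independently. The data hold more changed genes and replicates that deviate together, so these shares may not carry over to them. A simulated response ratio of 0.8 was returned as 0.796.

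Alternatives were RLE and upper-quartile scaling, no filter on low counts, DESeq2 1.42.0, limma-voom, the replicate block, the compared groups alone, an adjusted p under 0.01, and leaving out each library in turn. Correction for GC content and length, the same with the block, and leaving out processed pseudogenes were added after seeing the data.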

Results

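Gene expression was measured by RNA sequencing in C4-2 prostate cancer cells, a line derived from LNCaP that grows under castrate conditions. The design crossed an siRNA against PXN, which encodes the focal adhesion adaptor paxillin, with the androgen DHT. The 4 groups were nonspecific siRNA with vehicle, nonspecific siRNA with DHT, paxillin siRNA with vehicle and paxillin siRNA with DHT, with 3 libraries each. Totals per library ran from 11944906 to 25303242 counts for nonspecific vehicle and from 24207745 to 28298195 for nonspecific DHT. They ran from 25701219 to 29037657 for paxillin vehicle and from 26251814 to 32040465 for paxillin DHT. Over 9721 genes, the first principal component held 68.6% of the variance and separated DHT from vehicle, and the second held 18.4% and separated the siRNAs. On the second, replicates 1 to 3 lay at -5.6, -12.7 and -18.7 in paxillin vehicle and at -5.6, -9.8 and -15.3 in paxillin DHT. The nonspecific libraries lay at 9.4 to 13.2. The siRNA difference thus grew with the replicate number, which a fit with an additive replicate block does not model.

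PXN (chromosome 12, 120210439 to 120265771, GRCh38) followed the labels in every library. In vehicle it stood at 149, 139 and 151 CPM with nonspecific siRNA and at 16.7, 12.4 and 12.3 CPM with paxillin siRNA. In DHT the values were 136, 121 and 122 CPM against 14.2, 11.3 and 9.36 CPM. The siRNA lowered PXN by 90.5% in vehicle and by 90.8% in DHT, with log2 fold changes of -3.40 ± 0.12 and -3.44 ± 0.12 (SE) and edgeR quasi-likelihood Benjamini-Hochberg adjusted p-values of 7.4e-12 and 8.1e-12. TGFB1I1, which encodes the related protein Hic-5, had 0 to 7 counts per library and was not tested. LPXN, which encodes leupaxin, had log2 fold changes of 0.01 in vehicle and 0.12 in DHT (edgeR Benjamini-Hochberg adjusted p = 0.97 and 0.73).

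**Figure D1:**
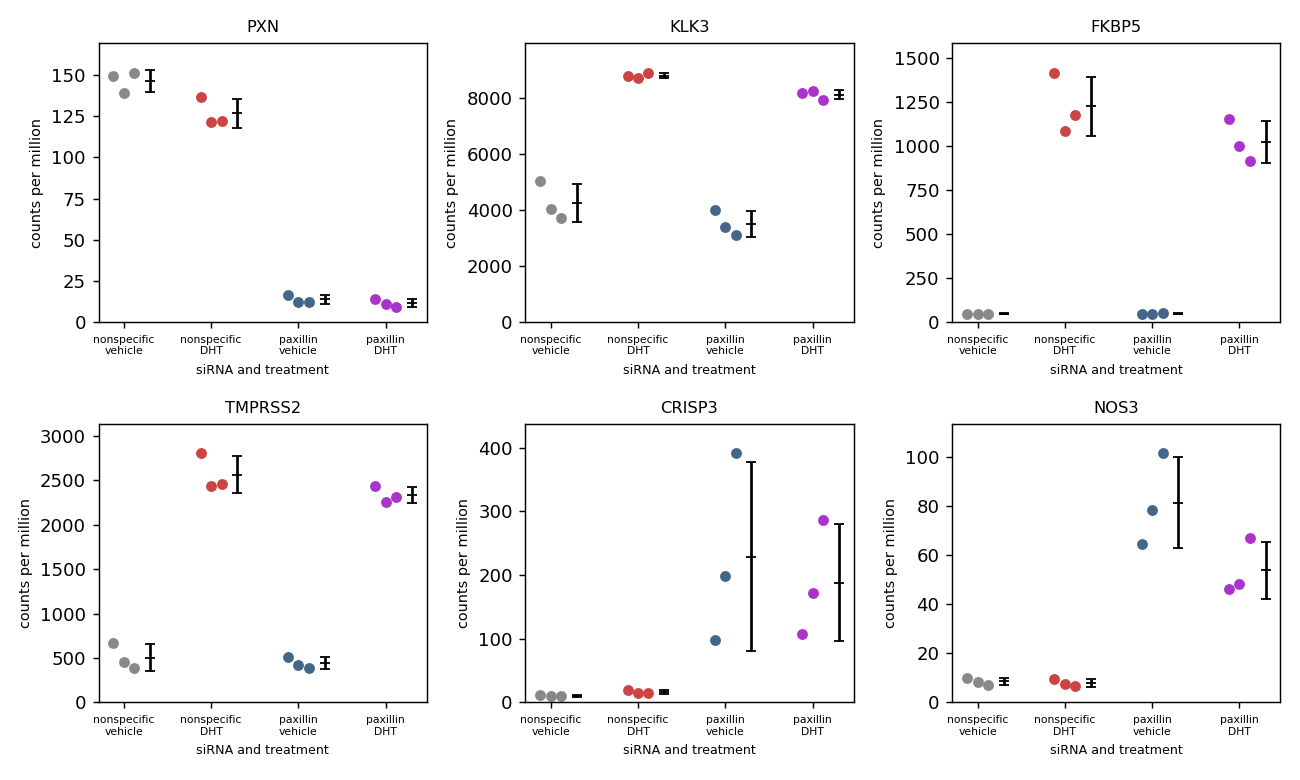
Level in CPM (y axis, from 0) of PXN, KLK3, FKBP5, TMPRSS2, CRISP3 and NOS3 in the 4 groups of siRNA and treatment (x axis), with points for the 3 libraries and a bar for the mean ± SD. PXN lies at 121 to 151 CPM with nonspecific siRNA and at 9.36 to 16.7 CPM with paxillin siRNA.

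The first comparison asked which genes respond to DHT when paxillin is present. With nonspecific siRNA, DHT raised well-known androgen-induced genes. FKBP5, a co-chaperone of steroid receptors (chromosome 6, 35573585 to 35728583), rose 25.8-fold from 47.5 ± 2.29 to 1230 ± 169 CPM (mean ± SD, n = 3 per group). TMPRSS2, a serine protease gene, rose 5.09-fold from 504 ± 149 to 2560 ± 207 CPM. KLK3, which encodes prostate-specific antigen (chromosome 19, 50854915 to 50860764), rose 2.07-fold from 4250 ± 689 to 8790 ± 83.7 CPM. In these 3 genes the edgeR quasi-likelihood Benjamini-Hochberg adjusted p was 3.9e-07 or lower.

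Altogether 6534 of 16115 genes (40.5%) changed, 3481 up and 3053 down, and 595 rose and 833 fell at least 2-fold. With upper-quartile scaling the split was 2707 up and 3896 down. The largest rises under the naming rule, which asks for a group mean of at least 5 CPM, were in genes almost silent in vehicle. SLC26A3, an anion exchanger, had 0 counts in vehicle and reached 6.92 ± 0.589 CPM, at least 149-fold higher. CCDC141 rose from 1 count over the vehicle group to 10.7 ± 1.23 CPM, a ratio of 691 with a 95% counting interval of 124 to 27300. CHRNA2, a nicotinic receptor subunit, rose 209-fold to 62.5 ± 2.48 CPM and STEAP4, a metalloreductase, 177-fold from 0.104 CPM. SLC2A3, a glucose transporter, rose from 0.0659 to 12.1 CPM and ADAM7 from 0.0794 to 6.38 CPM. The vehicle group held 4 counts each of SLC2A3 and ADAM7, and single vehicle libraries moved their folds. The fold of SLC2A3, 181, was 393 without nonspecific vehicle replicate 2, which left 1 count, and 110 without 3, and the log2 fold change of ADAM7, 6.57, was 7.22 without replicate 1, which left 2 counts, and 5.88 without 2. The count of CCDC141 lies in replicate 3, without which the vehicle group held 0 counts. SLC6A20, an amino acid transporter, had the largest fall under the naming rule, from 11.7 ± 1.21 to 0.472 ± 0.187 CPM with a log2 fold change of -4.65. PLD1 (phospholipase D1) fell 9.89-fold, SYTL2 8.91-fold, MYLK (myosin light chain kinase) 8.82-fold, SPTLC3 8.51-fold and UNC13C 8.40-fold. SLC2A3, MYLK, UGT2B15 and ORM1 have close paralogs or pseudogenes, so their counts are uncertain.

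Of the 38 androgen-induced genes, 36 rose and 2 did not pass (37 rose adjusted over the list alone), with a median log2 fold change of 2.23. ORM1, at 0 counts in vehicle, was at least 55.3-fold higher, and the median with ORM1 at that bound was also 2.23. Of the 12 androgen-repressed genes, 11 fell (11 adjusted over the list alone), among them UGT2B15, an androgen-glucuronidating enzyme, at -3.88, the chemokine receptor ACKR3 at -2.54 and the receptor kinase MET at -2.43. These 2 lists passed camera with adjusted p-values of 6.66e-30 and 8.06e-07 and kept their calls with an estimated correlation (0.0183 and 0.0194). No other list kept its call with an estimated correlation. Of the camera calls, fry lost only ribosomal protein (0.144), and it added ERK and immediate early (0.00037), focal adhesion (0.0046), neuroendocrine (0.0105) and NF-kappaB (0.0487) upward and TGF-beta (0.022) downward.

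Among lipid, polyamine and secretory pathway genes, more rose than fell, and these list calls were lost with an estimated correlation. Of 25 cholesterol synthesis genes, 21 rose and 2 fell (21 and 2 adjusted over the list alone), with HMGCS1 up 2.19-fold (camera adjusted p = 1.93e-06; adjusted p = 0.476 with an estimated correlation). Of 19 fatty acid synthesis genes, 10 rose and 2 fell (11 and 2 adjusted over the list alone), led by ACSL3 at 8.21-fold and ELOVL5 at 4.03-fold (camera adjusted p = 0.0117; adjusted p = 0.40 with an estimated correlation). Among 10 polyamine genes, 5 rose and 1 fell (7 and 1 adjusted over the list alone), and ODC1, SMS and SAT1 rose 6.28-, 5.81- and 5.36-fold (camera adjusted p = 0.000934; adjusted p = 0.191 with an estimated correlation). Hexosamine and glycosylation genes rose in 16 of 20 and fell in 3 (the same counts adjusted over the list alone), with ST6GALNAC1 up 7.14-fold (camera adjusted p = 4.05e-05; adjusted p = 0.191 with an estimated correlation). Endoplasmic reticulum folding genes rose in 17 of 20 (17 adjusted over the list alone), with PDIA5 up 3.04-fold (camera adjusted p = 4.79e-08; adjusted p = 0.322 with an estimated correlation).

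Mitosis genes fell in 18 of 34 and 1, CDK1, rose (18 and 1 adjusted over the list alone), with TOP2A, the replicative topoisomerase, down 1.58-fold (camera adjusted p = 0.000172; adjusted p = 0.515 with an estimated correlation). Of 38 DNA replication genes, 9 fell and 2 rose (7 and 1 adjusted over the list alone, and 16 and 1 over all genes with upper-quartile scaling; camera adjusted p = 0.123, and 0.04 without nonspecific vehicle replicate 2). Actin cytoskeleton genes rose in 12 of 23 and fell in 4 (13 and 4 adjusted over the list alone), with TPM1 up 1.71-fold and MYH10 down 1.72-fold (camera adjusted p = 0.0255, and 0.054 without nonspecific DHT replicate 1; adjusted p = 0.493 with an estimated correlation). Of 12 YAP targets, 8 fell and 1 rose (8 and 1 adjusted over the list alone), with ARHGEF17 down 1.65-fold and LATS2 up 1.62-fold (camera adjusted p = 0.0334; adjusted p = 0.191 with an estimated correlation). Hypoxia and glycolysis genes rose in 14 of 26 and fell in 3 (17 and 3 adjusted over the list alone), with the glycolytic genes HK2 and SLC2A1 up 1.96- and 1.92-fold and the carbonic anhydrase CA9 down 3.31-fold (camera adjusted p = 0.00412; adjusted p = 0.59 with an estimated correlation). Luminal epithelium genes rose in 9 of 17 and fell in 3 (9 and 3 adjusted over the list alone), with SPDEF up 4.49-fold and HOXB13 lower by a log2 fold change of -0.33 (camera adjusted p = 0.00828; adjusted p = 0.246 with an estimated correlation). Ribosomal protein genes rose in 12 of 54 (1 adjusted over the list alone, and 2 over all genes with upper-quartile scaling), with RPS15 up 1.31-fold (camera adjusted p = 0.00142; adjusted p = 0.78 with an estimated correlation).

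Other lists did not pass camera. Of 19 ERK and immediate early genes, 9 rose (9 adjusted over the list alone), with the phosphatase DUSP4 up 5.30-fold and MYC 1.69-fold (camera adjusted p = 0.0532, and 0.029 with the replicate block). It was under 0.05 without nonspecific vehicle replicate 1 (0.024), nonspecific DHT replicate 2 (0.044) or 3 (0.048), paxillin vehicle replicate 1 (0.042) or 3 (0.045), or paxillin DHT replicate 1 (0.044). None of the 13 mitochondrially encoded genes passed edgeR, with 4 at an unadjusted p under 0.05, and 5 fell with upper-quartile scaling (camera adjusted p = 0.0817, 0.038 downward with the replicate block, 0.041 without nonspecific vehicle replicate 3 and 0.0027 without nonspecific DHT replicate 3). In the remaining lists, up and down counts were 14 and 6 of 35 focal adhesion genes, 5 and 9 of 21 integrin and matrix genes, 2 and 6 of 11 TGF-beta and BMP genes, and 5 and 2 of 11 NF-kappaB and cytokine genes. They were 3 and 4 of 31 interferon response genes, 4 and 4 of 22 p53 targets, 4 and 4 of 15 BCL2 family genes, 5 and 9 of 24 ATF4 and amino acid genes, and 1 and 0 of 27 oxidative phosphorylation genes. They were 4 and 2 of 9 neuroendocrine genes, 1 and 2 of 9 mesenchyme and fibroblast genes, and 4 and 2 of 16 histone genes. Adjusted over the list alone, they were 15 and 6 in focal adhesion, 5 and 3 in NF-kappaB, and the same in the other 10 of these lists, and camera adjusted p-values of the 12 lists ran from 0.293 to 0.96. Single members moved strongly, such as THBS1, a matrix glycoprotein, up 11.5-fold, SDC4 down 3.73-fold, GDF15 up 4.57-fold and the transporter SLC43A1 up 4.35-fold. The test and mean differ in sign from the median for NF-kappaB, p53 and, for the mean, BCL2 family genes, and only 2 of 14 basal, immune and endothelial genes were measured (none called by edgeR, 0 at an unadjusted p under 0.05). With upper-quartile scaling the medians of the BCL2, oxidative phosphorylation and histone lists changed sign, and up and down counts were 4 and 7 for p53 targets, 1 and 3 for oxidative phosphorylation, 3 and 9 for ATF4 and 3 and 3 for NF-kappaB. PXN itself had a log2 fold change of -0.21 with DHT (edgeR Benjamini-Hochberg adjusted p = 0.12, and 0.015 with the replicate block). CCND1 rose 1.33-fold, and FOS and EGR1, near 1 CPM, had log2 fold changes of -0.16 and -0.02 (edgeR Benjamini-Hochberg adjusted p = 0.78 and 0.96).

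**Figure D2:**
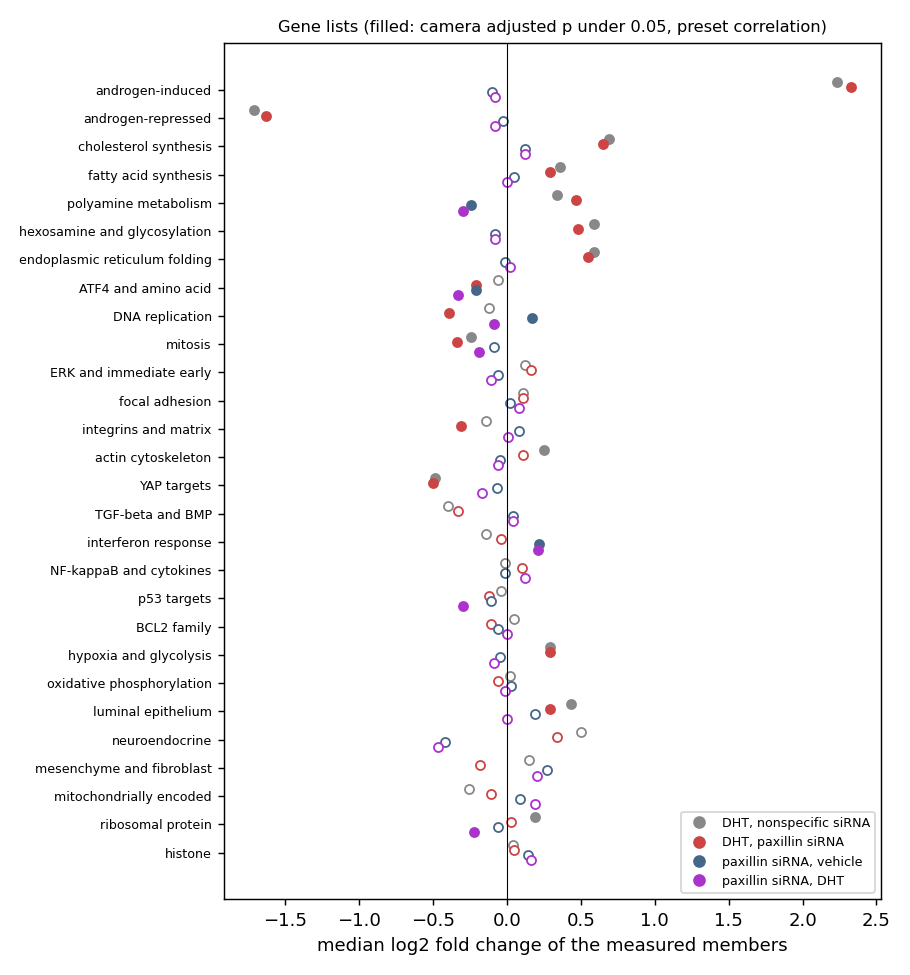
Median log2 fold change of the measured members (x axis) of the 28 gene lists that camera tested (y axis) in 4 comparisons, with filled points where camera with a preset correlation gave an adjusted p under 0.05. The androgen-induced list lies at 2.23 and 2.33 in the DHT comparisons and at -0.10 and -0.08 in the siRNA comparisons.

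The next comparison asked how cells given paxillin siRNA respond to DHT. The same androgen targets rose: FKBP5 21.4-fold from 47.7 ± 1.75 to 1020 ± 120 CPM, TMPRSS2 5.29-fold from 441 ± 66.4 to 2330 ± 94.1 CPM, and KLK3 2.31-fold from 3510 ± 465 to 8120 ± 156 CPM (mean ± SD, n = 3 per group). The edgeR quasi-likelihood Benjamini-Hochberg adjusted p was 6.4e-08 or lower for these 3 genes.

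In all, 6120 genes changed, 3234 up and 2886 down, with 575 rising and 819 falling at least 2-fold. With upper-quartile scaling the split was 2262 up and 3935 down. SLC26A3 again had 0 counts in vehicle and reached 7.29 ± 0.604 CPM, at least 208-fold higher. CCDC141 rose 366-fold, SLC2A3 157-fold, CHRNA2 146-fold to 134 ± 13.9 CPM, TTN (titin) 128-fold and STEAP4 127-fold. Without paxillin vehicle replicate 3, which left 2 vehicle counts of each, the log2 fold change of SLC2A3, 7.30, was 7.97, and TTN rose 317-fold. The largest falls under the naming rule were SLC6A20 at 24.5-fold, AMIGO2 at 12.5-fold, VAV3, a guanine nucleotide exchange factor, at 12.1-fold, MYLK at 9.52-fold, WNT5A, a noncanonical Wnt ligand, at 8.36-fold and PLD1 at 8.02-fold. Of the genes up here, 2576 (79.7%) were also up with nonspecific siRNA, where independent lists would share 698.6. Of the genes down here, 2090 (72.4%) were shared, against 546.8, and 7 genes were called in opposite directions, 2 of them up with nonspecific siRNA. These arms share no libraries. Their log2 fold changes correlated at Pearson r = 0.92 and Spearman rho = 0.84 across 13459 genes, which are not independent replicates.

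Androgen-induced genes rose in 36 of 38 (37 adjusted over the list alone) with a median log2 fold change of 2.33, and androgen-repressed genes fell in 11 of 12 (11 adjusted over the list alone) with a median of -1.63. Camera gave adjusted p-values of 4.42e-33 and 1.43e-07, and 0.0132 and 0.0152 with an estimated correlation. ORM1 had 3 counts over the vehicle group, and its ratio was 107 with a 95% counting interval of 36.2 to 520. Its log2 fold change, 6.53, was 7.38 without paxillin vehicle replicate 2, which left 1 count. DNA replication genes fell in 28 of 38 and rose in 1 (30 and 1 adjusted over the list alone), with the median at -0.39 (camera adjusted p = 5.96e-08; adjusted p = 0.244 with an estimated correlation). TK1, a thymidine kinase, fell 1.60-fold from 111 ± 5.84 to 69.2 ± 3.41 CPM, the cyclin CCNE2 1.59-fold and the replication factor MCM10 1.55-fold. Mitosis genes fell in 27 of 34 (28 adjusted over the list alone), with ESPL1 (separase) down 1.63-fold and KIF2C 1.44-fold (camera adjusted p = 8.22e-09; adjusted p = 0.261 with an estimated correlation).

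Here too, more of the lipid and secretory pathway genes rose than fell, and these list calls were lost with an estimated correlation. Up and down counts were 19 and 3 of 25 cholesterol synthesis genes (21 and 3 adjusted over the list alone), with HMGCS1 up 2.31-fold (camera adjusted p = 2.11e-06; adjusted p = 0.451 with an estimated correlation). They were 12 and 4 of 19 fatty acid synthesis genes (12 and 4 adjusted over the list alone), with ACSL3 up 7.08-fold (camera adjusted p = 0.00445; adjusted p = 0.268 with an estimated correlation). Polyamine genes rose in 6 of 10 (6 adjusted over the list alone), with SMS up 6.97-fold (camera adjusted p = 6.04e-05; adjusted p = 0.124 with an estimated correlation). Hexosamine and glycosylation genes gave 15 and 1 of 20 (15 and 2 adjusted over the list alone; camera adjusted p = 8.7e-06; adjusted p = 0.138 with an estimated correlation), and endoplasmic reticulum folding genes 17 and 0 of 20 (18 and 0 adjusted over the list alone; camera adjusted p = 7.21e-09; adjusted p = 0.244 with an estimated correlation). YAP targets gave 1 and 7 of 12 (1 and 7 adjusted over the list alone; camera adjusted p = 0.0111; adjusted p = 0.124 with an estimated correlation). Hypoxia and glycolysis genes gave 15 and 3 of 26 (17 and 3 adjusted over the list alone; camera adjusted p = 0.00156; adjusted p = 0.514 with an estimated correlation), and luminal genes 9 and 3 of 17 (9 and 3 adjusted over the list alone; camera adjusted p = 0.01; adjusted p = 0.244 with an estimated correlation).

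Integrin and matrix genes fell in 12 of 21 and rose in 3 (12 and 3 adjusted over the list alone), with SDC4 down 3.56-fold, ITGA2 down 2.04-fold and THBS1 up 8.74-fold (camera adjusted p = 0.0351; adjusted p = 0.59 with an estimated correlation). That call ended without paxillin vehicle replicate 3 (0.15) or paxillin DHT replicate 1 (0.051). ATF4 and amino acid genes fell in 11 of 24 and rose in 2 (12 and 4 adjusted over the list alone), with CHAC1 down 2.10-fold and PSAT1, a serine synthesis enzyme, 1.70-fold (camera adjusted p = 0.0423, and 0.054 with the replicate block; adjusted p = 0.59 with an estimated correlation). It ended without any 1 of 6 libraries: nonspecific vehicle replicate 1 (0.059), 2 (0.051) or 3 (0.061), nonspecific DHT replicate 2 (0.051), paxillin vehicle replicate 1 (0.11) and paxillin DHT replicate 3 (0.089). MYC had a log2 fold change of 0.26 (edgeR Benjamini-Hochberg adjusted p = 0.22), and 0.24 with the replicate block (0.0047). PXN had -0.25 (edgeR Benjamini-Hochberg adjusted p = 0.16, and 0.043 with the replicate block). Of the camera calls, fry lost ATF4 (0.128) and integrin and matrix (0.0772), and it added NF-kappaB (0.000602), ERK and immediate early (0.00102), focal adhesion (0.00311) and actin (0.00806) upward and BCL2 family (0.0275) downward. Among lists not called, the mean of the mesenchyme and fibroblast genes was 0.33 where their median and test were negative. The ribosomal protein and histone medians, 0.03 and 0.05, changed sign with upper-quartile scaling, and ribosomal protein genes passed camera upward without paxillin DHT replicate 3 (0.015).

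The third comparison asked what paxillin siRNA does without hormone. The samples hold no other siRNA against PXN and no rescue, and paxillin protein was not measured in them. Effects of lost paxillin therefore cannot be told apart from off-target effects of the siRNA, here or in the other comparisons. Paxillin siRNA in vehicle raised CRISP3, a secreted cysteine-rich protein (chromosome 6, 49727384 to 49744437), 22.7-fold from 10.2 ± 0.949 to 229 ± 149 CPM (mean ± SD, n = 3 per group), and NOS3, endothelial nitric oxide synthase (chromosome 7, 150990995 to 151014588), 9.70-fold from 8.59 ± 1.39 to 81.5 ± 18.6 CPM. DNASE1L3 rose 6.01-fold, VAV3 5.05-fold, GPNMB, a transmembrane glycoprotein, 4.73-fold and CLEC7A 4.28-fold. After PXN, the largest falls under the naming rule were S100P, a calcium-binding protein, at 4.32-fold, PIK3AP1, a phosphoinositide 3-kinase adaptor (chromosome 10, 96593312 to 96720514), at 3.16-fold from 45.0 ± 3.25 to 14.1 ± 4.03 CPM, GIPC3 at 2.74-fold, the fatty acid ligase ACSL4 at 2.55-fold and the ephrin receptor EPHA3 at 2.53-fold. Each had an edgeR quasi-likelihood Benjamini-Hochberg adjusted p of 8.0e-04 or lower. The log2 fold change of CRISP3, 4.50, was 3.88 without paxillin vehicle replicate 3, and that of S100P, -2.11, was -2.76 without paxillin vehicle replicate 1.

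In all, 3303 genes changed, 1727 up and 1576 down, of which 231 rose and 239 fell at least 2-fold. The count was 1966 without nonspecific vehicle replicate 2 and 1848 without paxillin vehicle replicate 3. FKBP5 had a log2 fold change of 0.01, TMPRSS2 -0.19 and CCND1 -0.06 (edgeR Benjamini-Hochberg adjusted p = 0.96, 0.39 and 0.57). KLK3 had -0.28 (edgeR Benjamini-Hochberg adjusted p = 0.073, and 0.0085 with the replicate block), and MYC had 0.26, or 0.27 with the block (0.28, and 0.0033 with the block). FOS and EGR1 had -0.62 and -0.38 (0.31 and 0.43). Of 38 androgen-induced genes, 8 rose and 6 fell (11 and 8 adjusted over the list alone; camera adjusted p = 0.935), with ELL2 and UAP1 down 1.85- and 1.56-fold and ABCC4 up 1.41-fold. The mean of that list was 0.10 where its median and test were negative. Signs also differed between mean, median and test for the androgen-repressed, fatty acid, endoplasmic reticulum folding and BCL2 lists, none of them called in vehicle.

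Camera called 4 lists in vehicle, and none with an estimated correlation. Of these, fry lost ATF4 (0.0591) and DNA replication (0.0926), and it added YAP targets downward (0.0107) and oxidative phosphorylation upward (0.0388). Polyamine genes fell in 4 of 10 and rose in 1 (5 and 1 adjusted over the list alone), with OAZ2 down 1.43-fold and AMD1 1.32-fold (camera adjusted p = 0.0267; adjusted p = 0.766 with an estimated correlation). ATF4 and amino acid genes fell in 8 of 24 and rose in 1 (14 and 1 adjusted over the list alone), with CTH, a cysteine synthesis enzyme, down 1.77-fold and ASNS, asparagine synthetase, 1.63-fold (camera adjusted p = 0.00574; adjusted p = 0.766 with an estimated correlation). DNA replication genes rose in 8 of 38 and fell in 1 (8 and 2 adjusted over the list alone), with the licensing factor CDT1 up 1.39-fold and E2F1 1.38-fold (camera adjusted p = 0.00574; adjusted p = 0.766 with an estimated correlation). Interferon response genes rose in 5 of 31 and fell in 1 (5 and 1 adjusted over the list alone), with IRF1 up 2.32-fold and OAS3 1.65-fold (camera adjusted p = 0.0338; adjusted p = 0.766 with an estimated correlation). The interferon call ended without paxillin vehicle replicate 3 (0.072) and with correction for GC content and length (0.061), an alternative added after seeing the data. Without paxillin vehicle replicate 1, cholesterol synthesis genes passed upward (0.033) and ribosomal protein genes downward (0.013).

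Adhesion genes moved singly in both directions. Focal adhesion genes gave 10 up and 4 down of 35 (12 and 5 adjusted over the list alone; camera adjusted p = 0.379). TLN2 (talin 2) rose 2.37-fold and FERMT1 (kindlin-1) 1.51-fold, and FERMT2 (kindlin-2) fell 1.60-fold and TES 1.57-fold. Integrin and matrix genes gave 4 up and 5 down of 21 (6 and 6 adjusted over the list alone; camera adjusted p = 0.789), with ITGA1 up 3.41-fold, LAMB3 up 3.99-fold, ITGAV down 1.74-fold and ITGB1 down 1.30-fold. JUN rose 2.10-fold and VIM (vimentin) 2.30-fold, and MET fell 1.96-fold. Libraries also differed with the siRNA. Processed pseudogenes took 542.8 to 646.7 CPM with paxillin siRNA and 669.7 to 921.3 CPM with nonspecific siRNA over both treatments. Over the tested copies alone the ranges overlap, as nonspecific vehicle replicate 1 held 545 CPM, within the 486.6 to 583.9 CPM with paxillin siRNA, and the other nonspecific libraries 699.9 to 752.1 CPM. After thinning to 11944906 counts, 19811 to 20786 symbols had a count with paxillin siRNA and 21247 to 22276 with nonspecific siRNA. Across 11476 coding genes, log2 fold change and GC content had Spearman rho = 0.31 in vehicle.

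**Figure D3:**
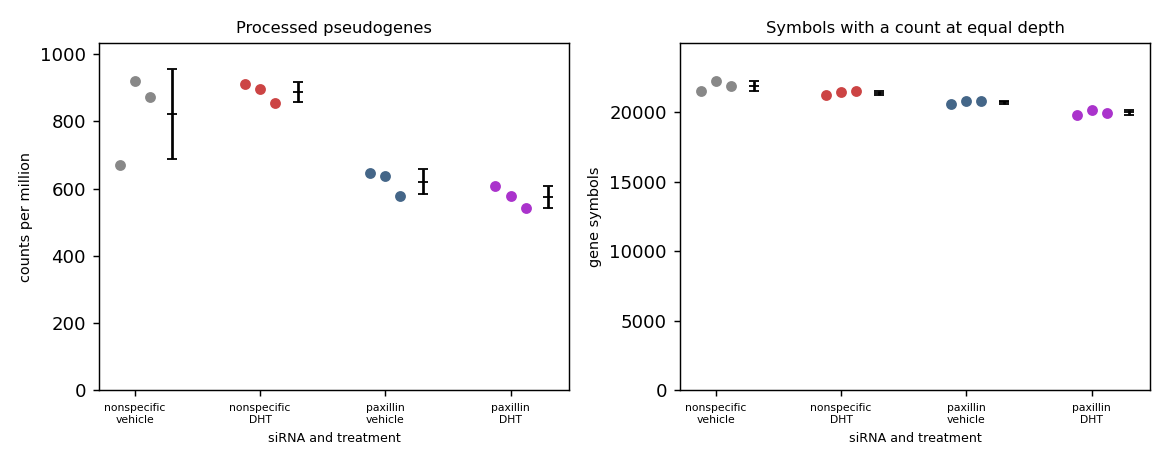
Summed processed pseudogenes in CPM (left y axis) and gene symbols with at least 1 count after thinning every library to 11944906 counts (right y axis), in the 4 groups of siRNA and treatment (x axis), with points for the 3 libraries and a bar for the mean ± SD. The paxillin siRNA libraries lie at 542.8 to 646.7 CPM and 19811 to 20786 symbols, below the nonspecific libraries. Over the tested copies alone, nonspecific vehicle replicate 1 lies within the paxillin range.

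The fourth comparison asked what paxillin siRNA does in the presence of DHT. CRISP3 rose 11.7-fold from 16.0 ± 2.97 to 188 ± 91.2 CPM, UNC13C 10.5-fold, NOS3 6.79-fold from 7.94 ± 1.63 to 53.8 ± 11.5 CPM and GPNMB 5.27-fold (mean ± SD, n = 3 per group). GSTA1, a glutathione transferase with close paralogs, rose 3.67-fold and BCAS1 rose by a log2 fold change of 1.85. S100P fell 3.93-fold and PIK3AP1 3.16-fold from 164 ± 14.7 to 51.8 ± 12.9 CPM. CHAC1, ASNS and CTH, members of the ATF4 and amino acid list, fell 2.03-, 1.80- and 1.78-fold. The edgeR quasi-likelihood Benjamini-Hochberg adjusted p of these genes was 0.0013 or lower. The other largest falls under the naming rule were the processed pseudogenes RPL13AP5, RPL18AP3 and RPL4P4, at 2.60- to 3.42-fold. They are uncertain because they may share reads with ribosomal protein genes.

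In all, 2149 genes changed, 1021 up and 1128 down, with 173 rising and 279 falling at least 2-fold. The replicate block gave 3486. The count was 1269 without nonspecific DHT replicate 2, 1386 without paxillin DHT replicate 2 and 1178 without paxillin DHT replicate 3. Of the genes up here, 637 (62.4%) were also up in vehicle, where independent lists would share 109.4. Of the genes down, 700 (62.1%) were shared, against 110.3, and 4 genes were called in opposite directions. The log2 fold changes of these arms, which share no libraries, correlated at r = 0.72 and rho = 0.65 across 13459 genes, which are not independent replicates. Processed pseudogenes were again lower in the paxillin siRNA libraries, and rho with GC content was 0.10.

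KLK3 had a log2 fold change of -0.12, TMPRSS2 -0.13 and CCND1 -0.12 (edgeR Benjamini-Hochberg adjusted p = 0.52, 0.59 and 0.28). FOS and EGR1 had -0.74 and -0.04 (edgeR Benjamini-Hochberg adjusted p = 0.26 and 0.94). FKBP5 had -0.26 (edgeR Benjamini-Hochberg adjusted p = 0.068, and 0.0093 with the replicate block) and MYC had -0.24 (0.36, and 0.0087 with the block). Of 38 androgen-induced genes, 5 rose and 3 fell (5 and 7 adjusted over the list alone, and 5 and 5 over all genes with upper-quartile scaling; camera adjusted p = 0.64). CHRNA2 rose 2.15-fold from 62.5 ± 2.48 to 134 ± 13.9 CPM and STEAP4 1.97-fold, and ELL2 fell 1.27-fold.

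Camera called 7 lists in DHT, and none with an estimated correlation. Of these, fry lost DNA replication (0.18) and ribosomal protein (0.178), and it added YAP targets (0.00551), neuroendocrine (0.0186) and actin (0.0473), all downward. ATF4 and amino acid genes fell in 17 of 24 (21 adjusted over the list alone) with a median log2 fold change of -0.33 (camera adjusted p = 1.07e-10; adjusted p = 0.422 with an estimated correlation). Mitosis genes fell in 9 of 34 (12 adjusted over the list alone; camera adjusted p = 5.21e-06; adjusted p = 0.584 with an estimated correlation) and DNA replication genes in 6 of 38 (8 adjusted over the list alone), with TK1 down 1.32-fold (camera adjusted p = 0.00948; adjusted p = 0.691 with an estimated correlation). Of 22 p53 targets, 9 fell and 2 rose (12 and 3 adjusted over the list alone), with GDF15, a stress cytokine, down 1.63-fold from 3430 ± 355 to 2110 ± 286 CPM and CDKN1A (p21) lower by a log2 fold change of -0.59 (camera adjusted p = 0.00315; adjusted p = 0.527 with an estimated correlation). Ribosomal protein genes fell in 4 of 54 (10 adjusted over the list alone, and 9 over all genes with upper-quartile scaling) with a median of -0.22, beside the lower pseudogene level in the same libraries (camera adjusted p = 2.14e-08; adjusted p = 0.691 with an estimated correlation). Polyamine genes fell in 5 of 10 and rose in 1 (5 and 1 adjusted over the list alone), with ODC1 down 1.39-fold and SMS up 1.47-fold (camera adjusted p = 0.0205, and 0.056 without nonspecific DHT replicate 1; adjusted p = 0.46 with an estimated correlation).

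Interferon response genes rose in 6 of 31 and fell in 2 (8 and 2 adjusted over the list alone), with OAS1 up 2.80-fold from 35 to 110 counts over the groups and HERC5 down 1.77-fold (camera adjusted p = 0.0434; adjusted p = 0.422 with an estimated correlation). The call of OAS1 (edgeR Benjamini-Hochberg adjusted p = 0.017) ended without nonspecific DHT replicate 1 (0.076) or 3 (0.071) or paxillin DHT replicate 2 (0.05) or 3 (0.065). The list call ended without nonspecific DHT replicate 1 (0.055) or 3 (0.064), paxillin vehicle replicate 3 (0.053) or paxillin DHT replicate 3 (0.079), and was at 0.05 with correction for GC content and length. With the replicate block, camera also called the mitochondrially encoded list upward (0.0727, and 0.04 with the block) and the neuroendocrine list downward (0.0534, and 0.04 with the block). The mitochondrially encoded list also passed without nonspecific DHT replicate 3 (0.00022) or paxillin DHT replicate 1 (0.038) or 2 (0.042). The neuroendocrine list passed without nonspecific DHT replicate 2 (0.023) or 3 (0.037) or paxillin DHT replicate 1 (0.039) or 2 (0.042). Actin genes (0.0534, and 0.041 with correction for GC content and length) passed downward without nonspecific DHT replicate 2 (0.023) or 3 (0.034) or paxillin DHT replicate 1 (0.021). YAP targets (0.0886) and hexosamine genes (0.0886) passed downward without paxillin DHT replicate 3 (0.049 each). Of the 13 mitochondrially encoded genes none passed edgeR, with 3 at an unadjusted p under 0.05, and of 9 neuroendocrine genes 2 fell, INSM1 3.05-fold and SYT1 3.72-fold. In DHT, SYT1 was low, at 0.34 to 0.9 CPM with nonspecific siRNA and 0.13 to 0.24 CPM with paxillin siRNA. Among adhesion genes, TLN2 rose 2.82-fold and NEDD9 1.47-fold, LAMB1 fell 1.59-fold, and ITGAV and ITGB5 fell 1.43- and 1.42-fold. The actin genes MYL9 and SRF fell 1.94- and 1.38-fold. JUN rose 1.81-fold and VIM 2.26-fold. Signs differed between mean, median and test for the androgen-repressed, endoplasmic reticulum folding, integrin, luminal and oxidative phosphorylation lists, none of them called in DHT.

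The last comparison asked whether paxillin siRNA alters the DHT response itself. Few genes passed the test of the interaction in the main fit, which ignores the pairing by replicate number. More passed with the replicate block, as given below. CDC42EP3, a CDC42 effector, rose with DHT by 1.03 on the log2 scale with nonspecific siRNA and by 2.12 with paxillin siRNA, an interaction of 1.09 ± 0.16 (SE). PGC, which encodes progastricsin (chromosome 6, 41736711 to 41754109), rose by 5.21 and 3.93, an interaction of -1.28 ± 0.21. KDM5A, a histone demethylase, fell by 0.64 with nonspecific siRNA, and its log2 fold change was -0.09 with paxillin siRNA. PCAT1, a noncoding RNA that the annotation lists as antisense and that is uncertain without the strand setting, rose by 1.47 with nonspecific siRNA, and its log2 fold change was 0.04 with paxillin siRNA.

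In all, 8 genes passed, 6 up and 2 down, with edgeR quasi-likelihood Benjamini-Hochberg adjusted p-values of 0.037 to 0.044, and 1435 had an unadjusted p under 0.05. The others were TMTC2 at 0.74, ZNF737 at 0.71, FAM129A at 0.61 and CITED2 at 0.55, each rising more with DHT under paxillin siRNA. DESeq2 called 57 genes, the replicate block 97, and limma-voom 0, with 1471 at an unadjusted p under 0.05. No gene passed edgeR without nonspecific vehicle replicate 2 or 3, nonspecific DHT replicate 2 or 3, paxillin vehicle replicate 2 or 3, or paxillin DHT replicate 2 or 3, with 1112 to 1522 at an unadjusted p under 0.05. The count was 4 without nonspecific DHT replicate 1 and 26 without paxillin vehicle replicate 1. These fits with a library left out did not use the replicate block. Interactions of the androgen targets were 0.16 for KLK3, -0.27 for FKBP5 and 0.06 for TMPRSS2 (edgeR Benjamini-Hochberg adjusted p = 0.79, 0.59 and 0.96). The 38 androgen-induced genes had a median interaction of -0.04 (camera adjusted p = 0.958), with 11 at an unadjusted p under 0.05. No member passed over all genes, and 1 was up and 1 down adjusted over the list alone. With the replicate block ELL2 passed at 0.55 and KCNN2 at -0.63 (edgeR Benjamini-Hochberg adjusted p = 0.027 and 0.0012), named after their values were seen. MYC had -0.50, and -0.51 with the replicate block (edgeR Benjamini-Hochberg adjusted p = 0.53, and 0.0094 with the block). CCND1, FOS, EGR1, LPXN and PXN had interactions of -0.06, -0.12, 0.33, 0.11 and -0.04 (edgeR Benjamini-Hochberg adjusted p = 0.86 to 0.98).

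Over genes called for the average DHT effect, the response with paxillin siRNA was 0.979 times that with nonspecific siRNA, with a jackknife spread of 0.045. The ratio was 0.930 without nonspecific DHT replicate 3 and 1.03 without paxillin DHT replicate 3. The jackknife leaves out single libraries as if independent, so it does not measure the spread of a ratio paired by replicate number. Camera called 5 lists, all downward, and neither the estimated correlation nor fry called any. Both of those tests were run without the replicate block, so variation shared by equal replicate numbers stays in their spread. None of the members of the 5 camera lists passed edgeR over all genes. With the replicate block 2 DNA replication genes did, MCM2 at -0.37 and TYMS at -0.39 (edgeR Benjamini-Hochberg adjusted p = 0.04 and 0.031), which were named after their values were seen. No ribosomal protein, mitosis or oxidative phosphorylation gene passed adjusted over the list alone. DNA replication genes had a median interaction of -0.27, with 17 of 38 at an unadjusted p under 0.05 and 6 down adjusted over the list alone (camera adjusted p = 3.78e-12; adjusted p = 0.569 with an estimated correlation). ATF4 and amino acid genes had -0.20, with 7 of 24 at an unadjusted p under 0.05 and 1 down adjusted over the list alone (camera adjusted p = 0.000166; adjusted p = 0.569 with an estimated correlation). Ribosomal protein genes had -0.17, with 2 of 54 at an unadjusted p under 0.05 (camera adjusted p = 3.28e-05, 0.053 without paxillin vehicle replicate 1 and 0.11 without paxillin DHT replicate 3; adjusted p = 0.928 with an estimated correlation). Mitosis genes had -0.13, with 5 of 34 at an unadjusted p under 0.05 (camera adjusted p = 0.000774, 0.077 without nonspecific vehicle replicate 1 and 0.074 without paxillin DHT replicate 1; adjusted p = 0.897 with an estimated correlation). Oxidative phosphorylation genes had -0.07, with 3 of 27 at an unadjusted p under 0.05 (camera adjusted p = 0.0176; adjusted p = 0.569 with an estimated correlation). That call ended without paxillin vehicle replicate 1 (0.062), paxillin DHT replicate 1 (0.074) or paxillin DHT replicate 3 (0.055), and with correction for GC content and length (0.054). The replicate block added the p53 targets, downward (0.0783, and 0.011 with the block). That list also passed without nonspecific vehicle replicate 1 (0.019), nonspecific DHT replicate 3 (0.006), paxillin vehicle replicate 3 (0.034) or paxillin DHT replicate 1 (0.018). Integrin and matrix genes (0.132) passed downward without nonspecific vehicle replicate 1 (0.019), nonspecific DHT replicate 2 (0.048), paxillin vehicle replicate 1 (0.023) or paxillin DHT replicate 3 (0.0062). Luminal genes (0.0783) passed downward without nonspecific vehicle replicate 1 (0.023) or nonspecific DHT replicate 2 (0.038), and cholesterol synthesis genes (0.524) without paxillin vehicle replicate 1 (0.045). Mitochondrially encoded genes (0.218) passed upward without nonspecific DHT replicate 3 (0.0011) or paxillin vehicle replicate 3 (0.012). Signs differed between mean, median and test for the androgen-repressed, hexosamine, TGF-beta and histone lists, none of them called. Interaction and GC content had Spearman rho = -0.31 across 11476 coding genes.

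**Figure D4:**
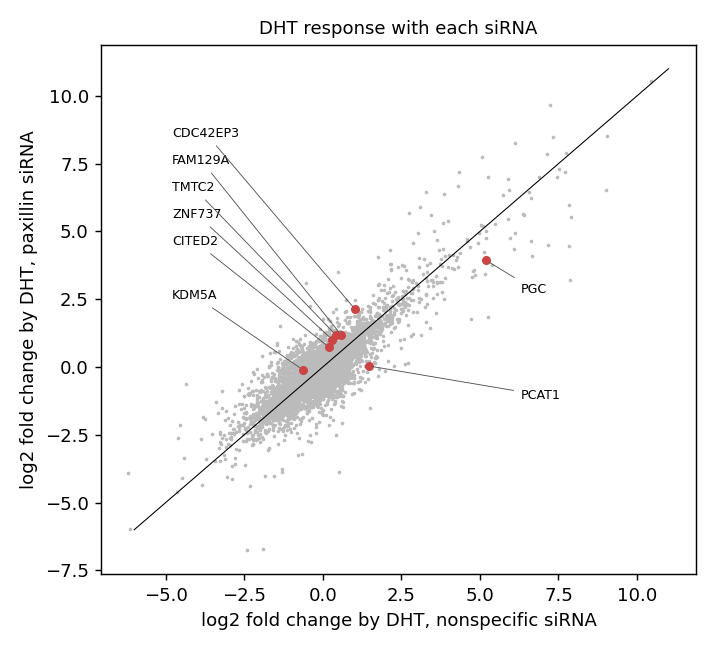
Log2 fold change by DHT with nonspecific siRNA (x axis) and with paxillin siRNA (y axis) for 16115 genes (grey points), with a line of equal response and the 8 genes past the interaction test in red. CDC42EP3 lies above the line at 1.03 and 2.12, and PGC below it at 5.21 and 3.93.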

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

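In this part, the fits with correction for GC content and length and the shares of the siRNA difference were chosen only after the data were seen. The genes and lists checked here were picked because they had passed in these data.

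In the test of the interaction itself, 8 genes passed, and camera with a preset correlation called 5 gene lists. Neither the estimated correlation nor fry called any list, and both were run without the replicate block. Interactions were 1.09 for CDC42EP3, 0.74 for TMTC2, 0.71 for ZNF737, 0.61 for FAM129A, 0.55 for KDM5A, 0.55 for CITED2, -1.28 for PGC and -1.43 for PCAT1, with edgeR quasi-likelihood Benjamini-Hochberg adjusted p-values of 0.037 to 0.044. With the replicate block the adjusted p-values of these 8 genes ran from 0.0012 to 0.0061, and with the block and correction for GC content and length from 7e-04 to 0.0072. With that correction but no block, the calls of FAM129A, ZNF737 and PCAT1 ended (edgeR Benjamini-Hochberg adjusted p = 0.052 each). Those of PGC (0.065) and TMTC2 (0.077) ended too. Leaving out a library ended each of these calls in at least 8 of the 12 fits, all of them without the replicate block. Over 100 drawn of the 200 assignments of the siRNA labels within each treatment, 7, the real one included, gave at least the real 8 genes, so chance is not excluded by them. The highest other count was 4907, which equals the number called for the siRNA effect averaged over treatments, because swapping the labels within 1 treatment turns the contrast into that effect. All 6 other assignments with as many genes keep unequal shares of the siRNA difference in the treatments, so their counts point to this structure of the samples. The 48 others with equal shares gave 0 genes at most, but they mix the siRNAs within groups, which widens the spread. None of the assignments was fitted with the replicate block, with which the real one gave 97 genes.

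For the simple comparisons, the 6 libraries allow 10 splits, too few for a share under 0.05. The real split gave 6534, 6120, 3303 and 2149 genes, for DHT with nonspecific siRNA, DHT with paxillin siRNA, paxillin siRNA in vehicle and paxillin siRNA in DHT. The highest other split gave 0 in each, but the other splits mix DHT with vehicle, or the siRNAs, within groups. That widens the spread, so their 0 genes are no evidence for the real grouping. Of the 9 other splits, 3 part all 3 pairs of equal replicate number, as the real one does, and 6 part 1 pair. In each comparison only 1 of the 10 splits, the real one, gave as many genes.

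DNA replication genes had a median interaction of -0.27. A trend on GC content and length would have moved the median above -0.1, but it was -0.25 after that correction with the replicate block, which argues against the trend as the whole cause. Without the shallow nonspecific vehicle library of 11944906 counts the median was -0.28, and it ran from -0.35 to -0.21 over all libraries left out, which argues against 1 library. The call rests on the preset correlation (adjusted p = 0.569 with an estimated correlation), so it may come from genes that vary together between libraries. A true difference of the DHT response with the siRNA stays open as a hypothesis.

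ATF4 and amino acid genes had a median interaction of -0.20 and a median of -0.33 with paxillin siRNA in DHT. The latter was -0.37 after correction for GC content and length with the replicate block, and -0.32 at the highest with 1 library left out, nonspecific DHT replicate 2. Both argue against those explanations as the whole cause. With an estimated correlation the adjusted p was 0.422, so coordinated variation between libraries may still be behind it, and an effect of the siRNA stays open.

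Ribosomal protein genes had a median interaction of -0.17 (adjusted p = 0.928 with an estimated correlation), and the camera call ended without paxillin vehicle replicate 1 (0.053) or paxillin DHT replicate 3 (0.11). Mitosis genes had -0.13 (0.897), and the call ended without nonspecific vehicle replicate 1 (0.077) or paxillin DHT replicate 1 (0.074). Oxidative phosphorylation genes had -0.07 (0.569), and the call ended without paxillin vehicle replicate 1 (0.062) or paxillin DHT replicate 1 (0.074) or 3 (0.055).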

How the results depend on the processing

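The fits with correction for GC content and length and without processed pseudogenes were chosen only after the data were seen.

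No called result of a named gene or gene list reversed in the fits that tested it. Lists were not tested with upper-quartile scaling, no filter, DESeq2, limma-voom or the compared groups alone, or without processed pseudogenes. PXN and the total DHT counts stayed on their side of 1.5 times under every alternative run. With upper-quartile scaling, however, both DHT comparisons turned from more genes up to more genes down. The interaction count of 8 became 142 with no filter on low counts (45 up, 97 down), 57 with DESeq2, 97 with the replicate block, 3 with correction for GC content and length and 69 with that correction and the block. It was 0 with limma-voom (1471 genes at an unadjusted p under 0.05) and 0 at an adjusted p under 0.01, as all 8 lie above 0.01 (1435 unadjusted), and 0 to 26 with 1 library left out. The count for paxillin siRNA in DHT, 2149, became 3486 with the block, 3752 with the block and that correction, 954 at an adjusted p under 0.01 and 1178 to 2417 with 1 library left out. In vehicle, 3303 became 1651 at an adjusted p under 0.01 and 1848 to 3524 with 1 library left out. The DHT response ratio was 0.922 over the androgen lists and 0.930 to 1.03 with 1 library left out. The slope over the lists weighs the largest fold changes most, among them that of ORM1, at 0 counts in nonspecific vehicle. Medians with nonspecific and paxillin siRNA were 2.23 and 2.33 for androgen-induced genes and -1.71 and -1.63 for androgen-repressed genes. The value of 0.922 alone thus does not show a weaker response of these genes. With an estimated correlation, gene list calls fell to 2 and 2 for DHT with nonspecific and paxillin siRNA, and to 0, 0 and 0 for paxillin siRNA in vehicle, in DHT and for the interaction, and fry gave 0 for the interaction. The cause of these changes was not tested, except that a stricter threshold lowers counts by construction. The estimated correlation and fry were not run with the replicate block.

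Counted as 1 result under 1 setting, other settings ended named gene calls in 211 of 5420 fits and started them in 29, and leaving out a library ended them in 476 of 6540 and started them in 5. These are 119 and 9 of the 545 named gene results for other settings, and 127 and 3 for libraries left out, of 506 results called. For gene lists, other settings ended calls in 56 of 840 fits and started them in 26, and leaving out a library ended them in 22 of 1680 and started them in 37. These are 39 and 19 of the 140 list results for other settings, and 9 and 16 for libraries left out. Members near 0 counts are limited by depth.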

Other observations

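In this part, the genes named, the tests of parent genes and of the parent-to-copy ratio, and the count of neighbouring genes were chosen only after the data were seen.

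Genes around CRISP3 on chromosome 6 were also higher with paxillin siRNA in vehicle. CRISP1 rose by 3.38 on the log2 scale and PKHD1 by 2.67 (edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 0.0011 and 0.0041), from 6 and 10 counts over the nonspecific vehicle group. CRISP2 had 2 counts there and 43 with paxillin siRNA, a ratio of 16.3 with a 95% counting interval of 4.24 to 139 (edgeR Benjamini-Hochberg adjusted p = 0.013). CRISP genes are paralogs, so reads shared between them are possible. On chromosome 21, UMODL1, ABCG1, TFF3, TFF1 and RSPH1 rose together, with TFF1, a secreted trefoil peptide, at 0.88 and TFF3 at 0.53. With the replicate block, further genes passed the interaction test. KCNN2, a potassium channel gene of the androgen-induced list, had -0.63, NFIB, a transcription factor gene, 0.60 and ANGPT2, which encodes an angiopoietin, -1.68 (edgeR Benjamini-Hochberg adjusted p = 0.0012, 0.0018 and 0.0031 with the block, against 0.30, 0.24 and 0.11 without it).

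A hypothesis is that genes raised by paxillin siRNA in vehicle lie next to each other more often than chance gives. Among 11571 adjacent pairs of tested genes that do not overlap in the annotation, 236 had both members up. In 10000 random reassignments of the calls among genes of similar expression the mean was 153.4 and the central 95% range 132 to 175 (permutation p = 1e-04, the smallest these permutations can give). After correction for GC content and length with the replicate block, 330 pairs rose against 252.5, with a range of 225 to 280 (permutation p = 1e-04, again the smallest they can give). Shared GC content is thereby not the whole cause, and coordinated change of neighbours may contribute. Read-through transcripts, transcripts that extend past the annotated ends and reads shared between neighbouring paralogs were not tested.

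Tested processed pseudogenes were lower with paxillin siRNA than in 5 of the 6 nonspecific libraries. Of 303 tested, 99 fell in vehicle, 121 in DHT and 83 in both, with medians of -0.64 and -0.96. The level does not follow the siRNA in every library, since nonspecific vehicle replicate 1 held 545 CPM of the tested copies, within the 486.6 to 583.9 CPM with paxillin siRNA, against 699.9 to 752.1 CPM in the other nonspecific libraries. With 1 library left out, 59 to 123 copies fell in vehicle and 89 to 145 in DHT. Coding genes matched on expression had a median of 0 ± 0.04 in vehicle (bootstrap error), which argues against low counts. In vehicle, the parents of the falling copies had -0.15 against -1.97 for the 92 copies with a tested parent. Those copies were picked for their fall in this comparison, which widens the gap, but all 303 copies had a median of -0.64. The values argue against lower parent expression as the whole cause in vehicle, and parents were not compared in DHT. The copies fell more where the parent was more abundant relative to the copy (Spearman rho = -0.48 across 274 copies, permutation p = 1e-05, the smallest 100000 permutations can give). Copies can share a parent and come from the same libraries, so they are not independent and this p can be too small. That test was respecified after a first version had shared values between the ratio and the fold change. The result is consistent with reads of abundant parents being assigned to copies to a different extent between libraries. Why this would follow the siRNA was not tested, and an effect of the siRNA on the cells stays open.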
